A study of Apostichopus japonicus with 12 samples.

How the data were processed

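Ribosome-depleted total RNA from the respiratory tree of Apostichopus japonicus was sequenced in 12 libraries, 3 for each of 4 treatments. Per the labels' protocols, RNA was extracted with phenol and chloroform, ribosomal RNA was removed with a kit designed for human, mouse and rat RNA, and libraries were made with a directional kit in which the second cDNA strand is digested, so that strand is marked. The values analysed were FPKM values deposited by the authors, 1 column per library, with replicates not pooled. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, Cufflinks and DESeq 1.16 were used. Their roles, the genome build, the annotation and the counting step, including whether it used strand, are not given in the sources used here. Where reads were counted without regard to strand, reads of a feature and of an antisense partner cannot be told apart, and reads of near-identical copies may have been split or lost. Groups were taken from the treatment labels, and each column was matched to its library by title. The temperature and oxygen level of the control group are not given in the sources used here. The oxygen level of the thermal group and the temperature of the hypoxic group are not given either. They were taken to be those of the control group. The averages over each stress, the interaction, and the terms control temperature and control oxygen rest on that assumption.

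FPKM divides a read count by feature length and library total, so depth was recovered from the deposited values themselves. Within a library each FPKM value is a whole number of reads times a factor set by the feature's length and the library's total. The 12 totals were found as the numbers for which the values of a feature in all libraries become whole reads at a shared length. At a tolerance of 0.001 reads, all 59494 features gave whole reads. With wrong totals 0% of 3000 features with reads in at least 4 libraries did, which is the range of 52959 features. The recovered reads summed to between 99.983% and 99.993% of the recovered totals, which ran from 20387909 to 28428042 reads. Tested on simulated data, the procedure found 12 of 12 totals exactly and all reads right at 99.97% of 11734 features with reads in at least 4 libraries. The reads of the other 6535 features are less certain, since 40.1% of 3000 of them gave whole reads with wrong totals too. In simulated features with at least 50 reads in each of 1, 2 or 3 libraries, and 0 in the rest, all reads were right at 9.3%, 83.3% and 91.9%, and otherwise too low. These 6535 features held 0.042% of the recovered reads, and 281 of them were among the features tested. Every feature named below had reads in more than 3 libraries. Intervals and floors from these reads (exact binomial intervals, and a floor of 3 reads) cover counting error only, since the reads carry no molecular identifiers. The 2 most abundant features took between 5.13% and 7.99% of a library's summed FPKM.

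Features with at least 0.5 FPKM in at least 3 of the 12 libraries were tested, 46763 in number. Values were taken as log2(FPKM + 0.5), and log2 changes are on that scale, which understates the change of features with low values. One limma model (version 3.58.1, R 4.3.3) with a mean for each of the 4 groups and a trend of variance on mean level gave the 6 pairwise comparisons and the interaction, with Benjamini-Hochberg adjustment over the features tested and a threshold of 0.05. These choices, the alternatives and the rule for named features were fixed before the data were examined. The averages of each stress over the levels of the other, fitted in the same model, were added afterwards. So was a test with limma's voom on the recovered reads. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, median-of-ratios and quantile scaling, a fit on only the groups compared, a block for replicate number, robust variance estimation, an added fold minimum of 2, and leaving out each library in turn. Permutation tests were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

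Named features were chosen by rule. Among features past the threshold whose libraries do not overlap between the sides compared, with a mean of at least 5 FPKM on either side, at most 2 with the largest rise and 2 with the largest fall were named per comparison. The rule had asked for named genes, but 0 of the AJAP and MSTRG identifiers matched the RefSeq gene table of assembly ASM3797524v1 used here. For the same reason the lists of heat shock, hypoxia, metabolic, immune and tissue marker genes fixed beforehand could not be applied, and no coordinates are given. No feature is called coding or noncoding, because the table states no class.

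The test was tried on simulated reads drawn from the means, totals and spread of the real libraries with 200 changed features. These were drawn only from better-covered features, by a minimum on mean reads, and the largest spreads were capped. The shares found below therefore do not cover features with few reads. For hypoxic against control, among 44498 features, it found 1.5%, 34.3% and 57.6% of log2 changes of 1, 2 and 3, with 62 true and 2 false calls. For low oxygen averaged over temperature, among 44564 features, it found 22.4%, 62.7% and 84.8%, with 113 true and 8 false calls. Changes of 2-fold in groups of 3 are thus mostly missed. No pair of replicates was a duplicate, since the chi-square per degree of freedom between replicates ran from 52.3 to 108.7.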

Results

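Transcript abundance was measured by RNA sequencing of ribosome-depleted RNA in the respiratory tree of the sea cucumber Apostichopus japonicus, the branched organ through which the animal takes up oxygen from sea water. The 12 libraries formed 4 groups of 3: a control group, a thermal group (26 °C), a hypoxic group (2 mg/L dissolved oxygen) and a group under both stresses. The table listed 59494 features, of which 28586 carried AJAP identifiers and 30908 carried MSTRG identifiers. It did not pair identifiers with gene names, so features are given here by identifier. The reads recovered over all features numbered 22036281, 20384391 and 23240088 in the control libraries, 28424597, 24776625 and 21934259 in the thermal libraries, 22705050, 23922220 and 23148065 in the hypoxic libraries, and 21035624, 22022667 and 21751594 under both stresses. A feature near 0.5 FPKM (fragments scaled to feature length in kilobases and to library size) rested on a median of 9 reads, a counting error of 33.3%. The labels do not say that replicates were separate animals, so all p-values measure only the spread between these libraries.

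Of the features, 46763 were expressed highly enough to be tested. Pearson correlations of log2 values across features, which are not independent replicates, ran from 0.849 to 0.861 within the control group, 0.851 to 0.864 within the thermal group, 0.881 to 0.894 within the hypoxic group and 0.851 to 0.871 under both stresses. Between groups they ran from 0.809 to 0.883, so libraries of different groups were in part as alike as replicates. MSTRG features took between 22.7% and 30.88% of the reads of a library.

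**Figure D1:**
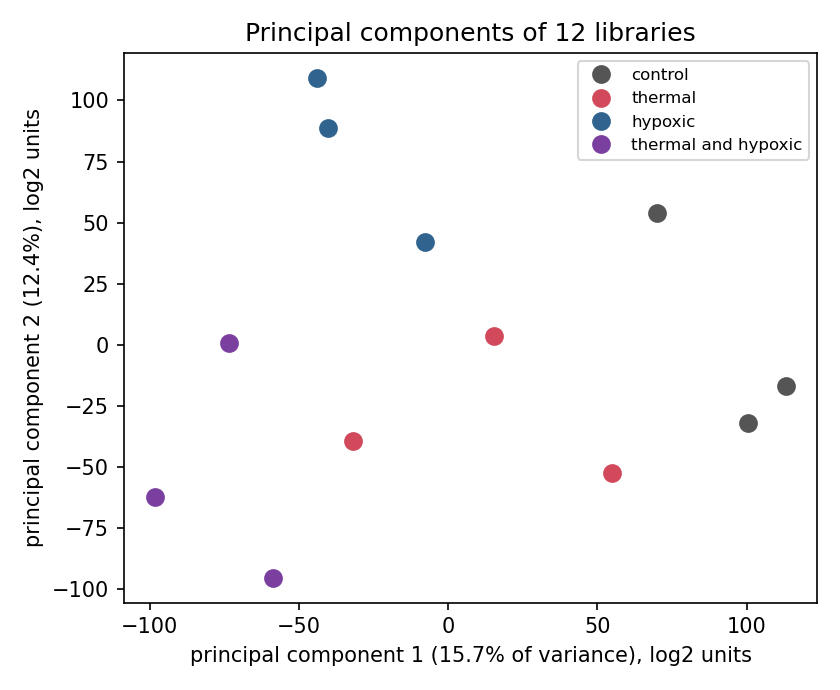
Scores of the 12 libraries on the first principal component (x axis, 15.7% of the variance) and on the next one (y axis, 12.4%), in log2 units; each point is a library and the colours mark the groups. The control libraries have the highest scores on the x axis (113.2, 100.4 and 69.9), and the libraries under both stresses have the lowest (-58.6, -98.1 and -73.4).

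The comparison of the hypoxic with the control group asked which transcripts respond to low dissolved oxygen. AJAP19978 rose from 14.1 ± 7.33 to 403 ± 206 FPKM (SD, n = 3 per group), a log2 change of 4.80 (SE 0.49, adjusted p = 0.0071). AJAP25532 rose from 0.988 ± 0.376 to 62.3 ± 50.6 FPKM, by 5.12 on the log2 scale (SE 0.81, adjusted p = 0.027). AJAP06951 went the other way, from 58.7 ± 38 to 2.55 ± 1.42 FPKM, and fell by 4.20 on the log2 scale (SE 0.51, adjusted p = 0.009). AJAP02469 was at 16.5 ± 8.09 FPKM in the control group and 0.409 ± 0.384 FPKM in the hypoxic group, and fell by 4.19 (SE 0.66, adjusted p = 0.027). Altogether 191 features passed limma's test at an adjusted p of 0.05, 124 higher and 67 lower in the hypoxic group, with a median absolute log2 change of 2.10. They comprised 140 AJAP features, 98 of them higher, and 51 MSTRG features, 26 of them higher. On the recovered reads limma's voom called 63 features, 49 higher and 14 lower, 59 of them among the 191. Of the named features AJAP19978 (adjusted p = 0.0084) and AJAP06951 (adjusted p = 0.018) passed there too. The count was 0 without hypoxic replicate 1 and 0 without hypoxic replicate 2. It was 109 without hypoxic replicate 3, 19, 29 and 73 without control replicates 1, 2 and 3, 89 without thermal replicate 1, and 93 and 91 without replicates 2 and 3 of the group under both stresses.

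The comparison of the thermal with the control group asked the same of warm water. AJAP04789 rose from 1.75 ± 1.35 FPKM in the control group to 101 ± 83.2 FPKM at 26 °C, a log2 change of 5.40 (SE 0.73, adjusted p = 0.044). MSTRG.5606 had 0 reads in the 3 control libraries and 19.4 ± 13.6 FPKM in the thermal libraries, which is at least 898-fold higher against a floor of 3 reads over the group. It also had 0 reads in the 3 libraries under both stresses, which were at 26 °C too, and heat averaged over oxygen did not call it (log2 change 1.70, SE 0.47, adjusted p = 0.15). AJAP28331 was at 76.8 ± 21.8 FPKM in the control group and 19.1 ± 1.45 FPKM in the thermal group, and fell by 1.94 on the log2 scale (SE 0.24, adjusted p = 0.044). These were 3 of only 8 features that passed limma's test, 5 higher and 3 lower, while 4804 had an unadjusted p under 0.05 where 2338 would be expected by chance. The 8 calls lay close to the threshold, with a smallest adjusted p of 0.0441, and voom called 0 (4714 at an unadjusted p under 0.05). The count was 2 without thermal replicate 1 or 3, 1 without replicate 3 of the group under both stresses, and 0 without any other library.

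The group under both stresses differed from the control group at 881 features, 420 higher and 461 lower, with a median absolute log2 change of 2.07. AJAP04789 again rose, to 365 ± 285 FPKM, a log2 change of 7.25 (SE 0.73, adjusted p = 0.0026). AJAP20068 stood at 67.5 ± 37.7 FPKM under both stresses, while the 3 control libraries together held 2 reads of it. The ratio of depth-scaled reads was 2030, with an exact 95% interval for counting error of 563 to 16800. AJAP07200 was at 78.2 ± 46.4 FPKM in the control group and 1.00 ± 0.704 FPKM under both stresses, and fell by 5.54 on the log2 scale (SE 0.83, adjusted p = 0.012). AJAP03163 fell by 6.96 (SE 1.24, adjusted p = 0.02) to 0.157 ± 0.138 FPKM, from a control mean of 346 ± 555 FPKM that rested mostly on control replicate 3 (986 FPKM, against 12.7 and 39.3 in the other two). The calls comprised 625 AJAP features, 292 of them higher, and 256 MSTRG features, 128 of them higher. Voom on the recovered reads called 399 features, 189 higher and 210 lower, 383 of them among the 881, and of the 4 features named for this comparison AJAP04789 passed there (adjusted p = 0.024). Without replicates 1, 2 and 3 of the group under both stresses the count was 348, 135 and 416. Without control replicates 1, 2 and 3 it was 220, 312 and 238, and without hypoxic replicate 2 it was 538.

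Low oxygen was also compared in warm water, by setting both stresses against heat alone. There limma called 0 features, with 4083 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0837, and voom called 0 (3969 unadjusted). The features of the hypoxic group were followed into this comparison. The means of the comparisons share no library, but the calls came from the model of all 12 libraries, so the spread of the warm libraries helped select the features. Of the 191 features, 169 (88.5%) moved in the same direction, with a median log2 change of 0.74 against 2.10 where they were called, and 94 had an unadjusted p under 0.05 in that direction against 0 in the opposite one. Of the 20 assignments of the 6 warm libraries to groups of 3, only the real one gave a share as large. Its exact permutation p was 0.05, one-sided, the smallest these assignments can give. Other assignments gave up to 87.4%, so a share nearly as large also arose without the real grouping. The highest other median change was 0.47. In a test added after seeing the data, features were called and followed in separate fits of 2 groups each. Of the 27 features so called, 25 (92.6%) moved in the same direction, 16 with an unadjusted p under 0.05 in that direction and 0 in the opposite one. Among the 20 assignments of the warm libraries 3 gave a share as large (exact permutation p = 0.15, one-sided). The median change in that direction was 1.23, and the highest other was 0.84. Across all 46763 features the low-oxygen changes at control temperature and in warm water correlated at r = 0.153 (exact permutation p = 0.057, two-sided). The permutations reassigned all 12 libraries and so took all groups as alike, heat included. That p-value therefore does not test the low-oxygen changes apart from heat. Among the features followed, AJAP19978 was at 25.0 ± 12.7 FPKM in the thermal group and 172 ± 24.2 FPKM under both stresses, a log2 change of 2.86 (SE 0.49, adjusted p = 0.084). Without thermal replicate 2 the count was 86, and without thermal replicate 1 it was 2.

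Heat in low oxygen, the comparison of both stresses with low oxygen alone, gave 16 features, 10 higher and 6 lower. AJAP13651 rose from 1.08 ± 0.292 FPKM in the hypoxic group to 65.4 ± 43.2 FPKM under both stresses, a log2 change of 5.04 (SE 0.72, adjusted p = 0.046). MSTRG.43287 rose from 0.176 ± 0.222 to 46.0 ± 54.5 FPKM, by 5.30 (SE 0.77, adjusted p = 0.046), with 108 FPKM in replicate 1 and 5.93 FPKM in replicate 2. AJAP13526 held 159 ± 18.3 FPKM in the hypoxic and 155 ± 8.25 FPKM in the control group, and 23.5 ± 6.32 FPKM under both stresses. It fell by 2.76 against the hypoxic group (SE 0.31, adjusted p = 0.019). MSTRG.58781 had 0 reads in the 3 libraries under both stresses and 12.1 ± 4.16 FPKM in the hypoxic group, at least 77-fold lower against 3 reads over the group. Voom called 1 feature here, and none of the 4 named features passed it (adjusted p = 0.27 for MSTRG.43287, 0.20 for AJAP13651, 0.10 for MSTRG.58781 and 0.058 for AJAP13526). Leaving out control replicates 1, 2 and 3 gave 3, 10 and 3 features, hypoxic replicates 1, 2 and 3 gave 3, 1 and 1, thermal replicates 1 and 2 gave 2 and 49, and replicates 1 and 2 under both stresses gave 4 and 7.

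The thermal and hypoxic groups, set against each other, differed at 42 features, 17 higher and 25 lower in the thermal group. With median-of-ratios scaling the split was 15 and 35, and the median log2 change of all features went from 0.134 to 0.033. AJAP04318 held 8.54 ± 3.36 FPKM in the thermal and 245 ± 128 FPKM in the hypoxic group, and was lower in the thermal group by a log2 change of -4.71 (SE 0.70, adjusted p = 0.031). AJAP25349 had 1 read in the 3 thermal libraries together and 23.1 ± 17.1 FPKM in the hypoxic group, a ratio of depth-scaled reads of 1340 (exact 95% interval 241 to 53200). AJAP20562 was higher in the thermal group, at 24.2 ± 15.1 against 1.46 ± 1.00 FPKM, a log2 change of 3.60 (SE 0.46, adjusted p = 0.018), and its control level was 26.9 ± 5.18 FPKM. MSTRG.26801 was at 9.16 ± 7.21 FPKM in the thermal, 0.0777 ± 0.09 FPKM in the hypoxic and 8.37 ± 3.47 FPKM in the control group, a log2 change of 3.79 between the stressed groups (SE 0.55, adjusted p = 0.031). Voom called 33 features, 12 higher and 21 lower, 27 of them among the 42, but none of the 4 named here, and a fit on only the 2 groups compared called 0. The count was 3, 3 and 9 without hypoxic replicates 1, 2 and 3, 7 and 8 without thermal replicates 1 and 3, 25 without control replicate 3, and 19 and 23 without replicates 2 and 3 under both stresses.

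**Figure D2:**
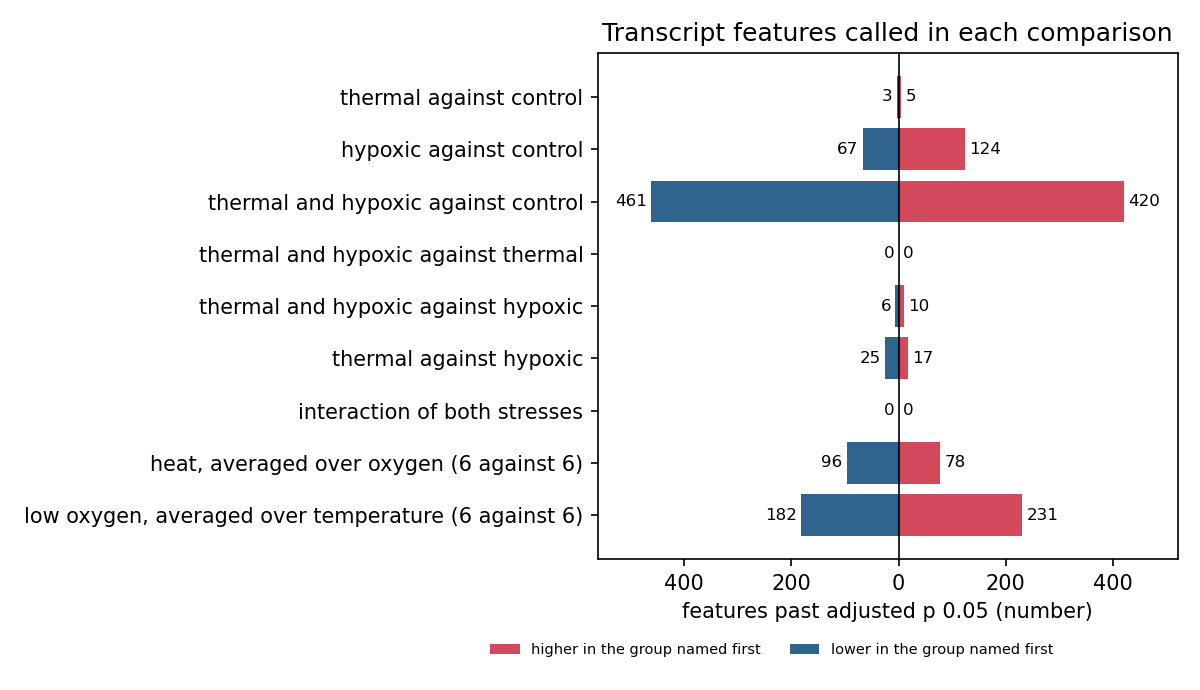
Number of features past an adjusted p of 0.05 (x axis, log2 values tested with limma) in each comparison (y axis), with features higher in the group named first to the right of 0 and lower ones to the left; every bar comes from the model of all 12 libraries. Both stresses against the control gave 420 higher and 461 lower features, and heat alone gave 5 and 3.

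The 4 groups were taken to cross temperature with oxygen, although the labels give no temperature for the hypoxic group. They give no oxygen level for the thermal group either. On that reading each stress was also averaged over the levels of the other, 6 libraries against 6. This comparison was added after the other results had been seen. Low oxygen changed 413 features, 231 higher and 182 lower, with a median absolute log2 change of 1.46. AJAP19978 rose from 19.6 ± 11 to 288 ± 182 FPKM (SD, n = 6), by 3.83 on the log2 scale (SE 0.34, adjusted p = 0.0036), and MSTRG.87467 rose from 0.609 ± 0.51 to 8.91 ± 6.24 FPKM, by 2.91 (SE 0.34, adjusted p = 0.0065). AJAP07200 fell by 4.37 (SE 0.59, adjusted p = 0.011), from 65.2 ± 38.3 to 3.66 ± 4.72 FPKM, and MSTRG.128783 fell by 3.61 (SE 0.53, adjusted p = 0.015), from 20.7 ± 12.6 to 1.47 ± 1.64 FPKM. Voom called 278 features, 166 higher and 112 lower, 257 of them among the 413, with AJAP19978 (adjusted p = 0.0046) and MSTRG.87467 (adjusted p = 0.024) past the threshold and the other two not. The count was 156 and 213 without control replicates 1 and 2, 151, 725 and 145 without thermal replicates 1, 2 and 3, 160 and 118 without hypoxic replicates 1 and 2, and 88 and 184 without replicates 2 and 3 under both stresses.

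Heat averaged over oxygen changed 174 features, 78 higher and 96 lower, with a median absolute log2 change of 1.62. AJAP04789 rose from 6.72 ± 8.76 to 233 ± 237 FPKM (SD, n = 6), a log2 change of 5.19 (SE 0.52, adjusted p = 0.0057). AJAP13651 rose from 0.692 ± 0.474 to 43.8 ± 37.9 FPKM, by 4.74 (SE 0.51, adjusted p = 0.007). AJAP12499 was at 300 ± 119 FPKM in the control and 282 ± 61.6 FPKM in the hypoxic group, and at 89.1 ± 23.8 FPKM in the thermal group and 44.8 ± 39.6 FPKM under both stresses. It fell by 2.37 with heat (SE 0.38, adjusted p = 0.028). AJAP21839 fell by 2.40 (SE 0.35, adjusted p = 0.024), from 16.3 ± 7.24 to 3.10 ± 2.37 FPKM. Voom called 158 features, 56 higher and 102 lower, 116 of them among the 174, with AJAP04789 (adjusted p = 0.021), AJAP12499 (adjusted p = 0.021) and AJAP21839 (adjusted p = 0.043) past the threshold and AJAP13651 (adjusted p = 0.074) not. Without control replicates 1, 2 and 3 the count was 42, 45 and 29, without thermal replicates 1, 2 and 3 it was 53, 51 and 108, without hypoxic replicates 1, 2 and 3 it was 29, 26 and 26, and without replicates 1 and 2 under both stresses it was 45 and 40.

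**Figure D3:**
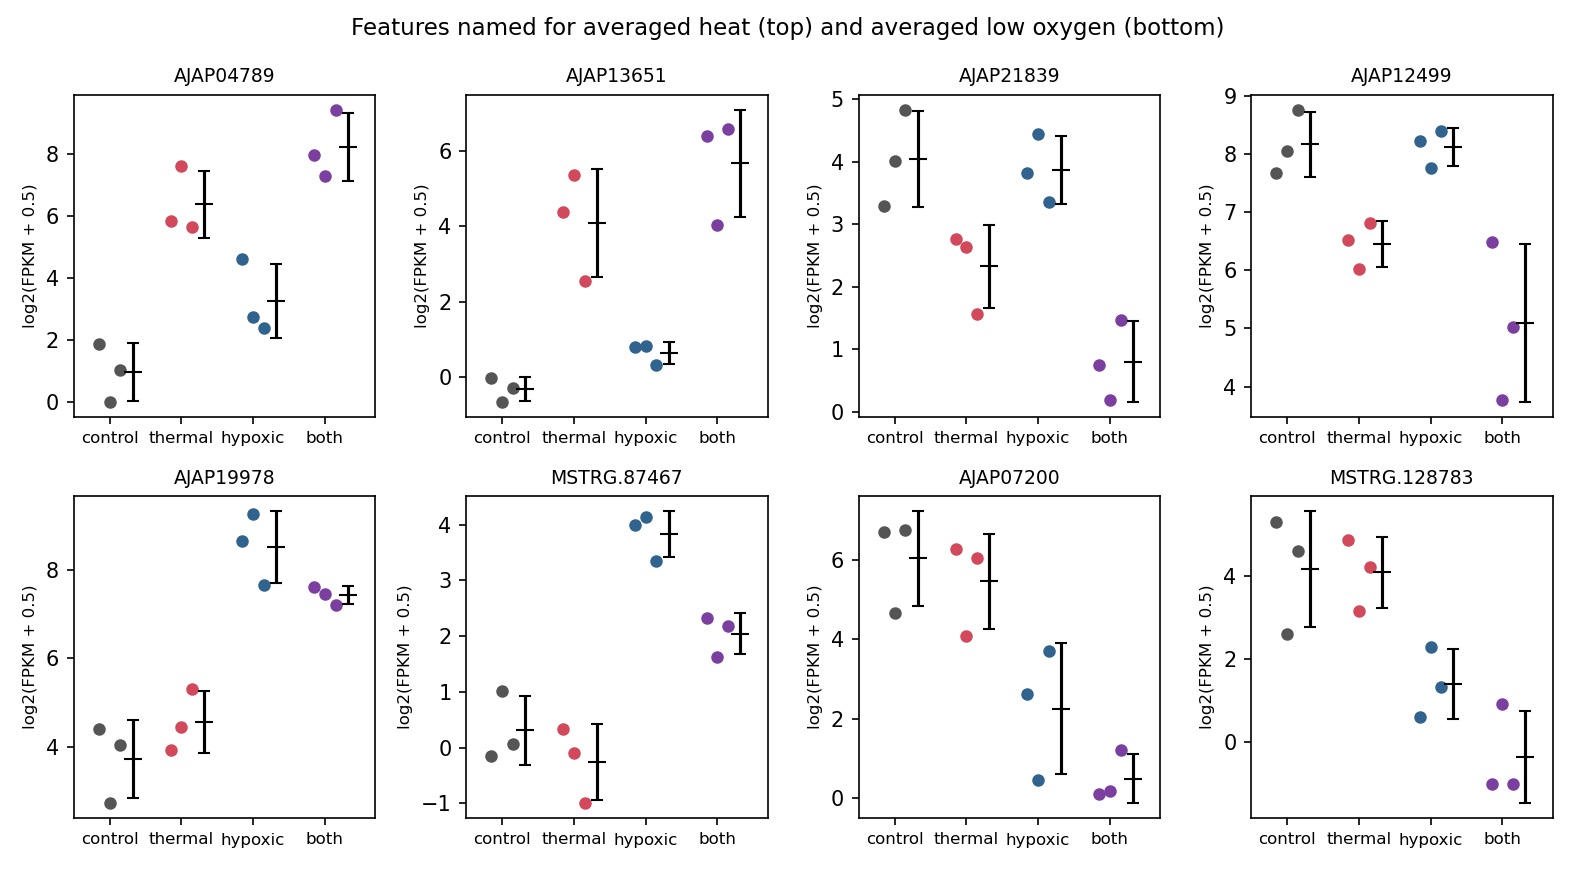
Abundance in each library, as log2(FPKM + 0.5) on the y axis, of the features named for the averaged comparisons, under heat (top row) and low oxygen (bottom row), by group on the x axis; they have the largest rises and falls among called features at 5 FPKM or more on either side whose libraries do not overlap. Points are libraries, and the black mark and bar beside them give the mean and SD of 3 libraries; AJAP19978, with group means of 14.1, 25.0, 403 and 172 FPKM in the control, thermal, hypoxic and combined groups, lies higher in the 6 low-oxygen libraries than in the other 6.

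The interaction asked whether the change under both stresses differed from the sum of the changes under each on the log2 scale. Limma called 0 features, with 3587 at an unadjusted p under 0.05 against 2338 expected by chance and a smallest adjusted p of 0.347, and voom called 0 (3371 unadjusted). Across all features the interaction took 9.6% of the sum of squares. The median over 369600 assignments of the 12 libraries to groups was 8.8% (exact permutation p = 0.28). The excess over 2338 is thus no sign of an interaction by itself. Among named features the interaction estimates reached -6.63 (SE 0.95, adjusted p = 0.35) for MSTRG.5606, -5.22 (SE 0.91, adjusted p = 0.37) for MSTRG.58781 and 4.24 (SE 0.78, adjusted p = 0.48) for MSTRG.26801, and were -1.94 (SE 0.69, adjusted p = 0.58) for AJAP19978 and -0.42 (SE 1.03, adjusted p = 0.95) for AJAP04789. Departures from a plain sum of several log2 units thus did not pass the adjustment, and the count of 0 does not show that the changes add up. The count was 2 without control replicate 3.

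The calls against the control overlapped. The hypoxic group and the group under both stresses shared 56 higher and 37 lower features, where independent lists would share 1.1 and 0.66. Heat, with only 8 calls, shared 4 higher and 3 lower features with both stresses (0.045 and 0.03 for independent lists). With low oxygen it shared 0 higher and 2 lower features (0.013 and 0.0043). Of the 191 features called under low oxygen, 175 (91.6%) moved the same way under heat, against the same controls. In limma's test 92 had an unadjusted p under 0.05 in that direction and 2 in the opposite one. AJAP06951 is an example of a shared fall, at 58.7 ± 38 FPKM in the control group and 5.82 ± 2.76, 2.55 ± 1.42 and 1.34 ± 0.444 FPKM in the thermal, hypoxic and combined groups, although its log2 change under heat, -3.13, had an adjusted p of 0.084. These comparisons use the same control libraries. The log2 changes across features correlated at 0.593 for low oxygen and both stresses, 0.602 for heat and both stresses, and 0.545 for heat and low oxygen, where simulated unchanged groups gave 0.502. The covariances were 0.392, 0.371 and 0.308 against a simulated 0.201, and the same direction was seen at 70.7%, 71.5% and 68% of features against 66.6%. Groups of 3 controls could not be split so as to leave at least 2 in each part, and part of the excess may come from the shared controls. The simulation gave all groups the same spread, but the control libraries lay farthest apart. Their mean squared log2 distance per feature was 1.301, against 1.242, 1.024 and 1.233 in the thermal, hypoxic and combined groups. A wider spread of shared controls raises the correlation without any response, so the simulated values may be too low. The simulation also drew each feature independently, while features of a real library are not independent. It therefore gives no range that chance could produce, and the excess alone cannot be read as a shared response.

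AJAP features were called at a higher rate than MSTRG features. Under low oxygen 0.617% of the 22691 AJAP features tested and 0.212% of the 24072 MSTRG features passed, and under both stresses 2.75% and 1.06%. Averaged over temperature, low oxygen changed 1.38% of AJAP and 0.415% of MSTRG features, and heat averaged over oxygen changed 0.546% and 0.208%. The classes differed in level, with a median of 6.37 FPKM for AJAP and 1.51 FPKM for MSTRG features, and in spread, with median SDs within groups of 0.49 and 0.73 log2 units. Within ranges of level the ratio of AJAP to MSTRG rates was smaller and was not always above 1. Under both stresses the rates for AJAP and MSTRG features were 0.201% and 0.333% below 1 FPKM, 1.01% and 0.469% from 1 to 2, 1.91% and 1.32% from 2 to 5, 2.61% and 1.94% from 5 to 10, 3.83% and 3.73% from 10 to 50, and 6.92% and 3.90% at 50 FPKM and above. Under low oxygen they were 0% and 0.0918%, 0.155% and 0.0937%, 0.225% and 0.132%, 0.319% and 0.323%, 1.04% and 0.972%, and 1.99% and 1.42% in the same ranges. Whether a feature is a messenger RNA or a long noncoding RNA, the classes named in the series title, was not determined here.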

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

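Voom on the recovered reads and the averaged comparisons were added after the data had been seen; every other setting was fixed beforehand. The averaged counts stayed within 1.5 times under other pseudocounts, a filter at 2 FPKM, other scalings, robust variances, an added fold minimum and voom. Pairwise counts moved more. Heat alone (8 features) gave 0 with a pseudocount of 0.1, a filter at 2 FPKM, median-of-ratios scaling, quantile scaling, only the 2 groups compared, and voom, and 19 with no filter. Low oxygen alone (191) gave 89 with no filter, 27 from only its 2 groups and 63 by voom. Both stresses against control (881) gave 562 with no filter, 159 from only their 2 groups and 399 by voom. Both stresses against low oxygen (16) gave 3 with no filter, 8 with a filter at 2 FPKM, 6 with median-of-ratios scaling, 3 with quantile scaling, 5 with robust variances, 4 from only the 2 groups and 1 by voom. Thermal against hypoxic (42) gave 0 from only the 2 groups. With no filter the averages gave 99 for heat (174) and 274 for low oxygen (413). Without a filter 59494 features share the adjustment, and a fit on only 2 groups has fewer libraries to estimate the spread; for the other settings the cause was not tested.

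Replicate numbers do not pair these libraries: deviations of libraries with the same number correlated between -0.08 and 0.086 across groups, and 3 of 12 libraries correlated best with their own number. With the number as a block, the counts were 0 for heat, 79 for low oxygen, 600 for both stresses, 1 for both against heat, 7 for both against low oxygen, 6 for thermal against hypoxic, 69 and 268 for averaged heat and low oxygen, and 0 for the interaction.

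Leaving out 1 library at a time gave 0 to 2 features for heat, 0 to 242 for low oxygen, 135 to 1016 for both stresses, 0 to 86 for both against heat, 1 to 49 for both against low oxygen, 3 to 51 for thermal against hypoxic, 0 to 2 for the interaction, 26 to 135 for averaged heat and 88 to 725 for averaged low oxygen. Fewer libraries then estimate the spread, and the cause of each change was not tested. No named log2 change reversed in any setting run. Of 27, 24 stayed past the threshold with a pseudocount of 1, 23 with 0.1, 22 with no filter or a filter at 2 FPKM, 21 with either scaling, 17 with the block and 8 by voom, as did 5 of 19 from only 2 groups and 202 of 324 with a library left out. Gene list tests (camera and fry) were not run, since no identifier matched a name. The alternatives planned for a deposited count table were not run either, and voom was the only test run on the recovered reads. Depth limits features near 0.5 FPKM, which rest on about 9 reads.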

Other observations

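The tests of depth and spread below, and those for the low oxygen and heat parts of the control offset, were set up after the results had been seen. Some features were present in some libraries and nearly absent from others. By recovered reads, 133 features had either at least 50 reads or at most 1 in every library, but reads were checked only for features above 0 in at least 4 libraries. Among those, 57 features met the limits, 34 of them AJAP features, and 22 of the 57 were absent, at that limit, from 1 library alone. By listed FPKM, a rule chosen after seeing the data, 63 features were at either 0 or at least 5 FPKM in every library, and 43 of these were present in 1 library alone, 37 of them MSTRG features, with up to 44.2 FPKM. Each library had between 1 and 7 such features of its own. The pattern followed a single group in few cases: 1 of the 57 and 0 of the 63 were present in, or absent from, exactly the 3 libraries of 1 group. Features present in, or absent from, both groups under the same stress were not counted.

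The control libraries scored highest on the first principal component. By squared shift between group means, less the part spread adds, the control group lay at 0.106 from the thermal, 0.224 from the hypoxic and 0.301 from the combined group. The thermal and hypoxic groups lay at 0.157 from each other. The combined group lay at 0.102 from the thermal and 0.168 from the hypoxic group. By these values the thermal group lay nearer to the control group than to the hypoxic group. If an offset of the 3 controls were the whole cause of the group differences, the 9 stressed libraries should not part by treatment. They did: the sum of squares between the thermal, hypoxic and combined groups was 31.3% of their total, against at most 29.9% in the other splits of these 9 libraries into groups of 3, so that 1 of 280 splits was as large (exact permutation p = 0.0036, the smallest these splits can give), which argues against the controls as the whole cause. For the parts the evidence is weaker: the low-oxygen change at control temperature and that in warm water, which share no library, correlated at r = 0.153 across features (rho 0.146, exact permutation p = 0.057, two-sided), and the heat changes at control and low oxygen at r = 0.119 (rho 0.113, exact permutation p = 0.13). The permutations for these correlations reassigned all 12 libraries and so took all groups as alike. They do not test the changes under 1 stress apart from the other stress. How much of either change an offset of the controls accounts for stays open, as does a holding tank or day shared by a group, which the labels do not describe.

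Far more features were called against the control under both stresses (881) than under heat alone (8). At an unadjusted p under 0.05 the counts in limma's test were closer, 7294 and 4804, with 2338 expected by chance. Of the 881 features, 849 (96.4%) moved the same way under heat, 569 of them at an unadjusted p under 0.05. Both comparisons use the same control libraries, which by itself favours the same direction. Lower depth of the thermal libraries does not account for the gap in called features, since their mean library total was 115.9% of that under both stresses. Wider spread among them would raise the standard error of every comparison and not only that of heat. The reason is that the model shares each feature's estimate of spread among all groups. Both comparisons thus have the same standard error. The thermal replicates lay at 100.8% of the mean squared distance seen under both stresses. Scaling moved the balance little: under the deposited, median-of-ratios and quantile scalings heat gave at most 0.91% as many calls as both stresses. Less the part spread adds, the squared shift from the control was 0.301 under both stresses and 0.106 under heat, a ratio of 2.84. The gap in called features thus goes with a larger observed shift. Whether that shift is larger beyond chance stays open. Of the 10 splits of these 6 libraries, 2 gave a ratio as large, the highest other being 2.89, and 10 splits are too few to exclude chance. The direct comparison of both stresses with heat gave 0 features, but tests of groups of 3 mostly miss changes of 2-fold.

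A hypothesis that features with consecutive AJAP numbers, if these follow genome order, change together was not borne out. Under both stresses the log2 changes of such pairs correlated at r = 0.004, within the range of 1000 shuffled orders (up to 0.024). Both members were called in 17 pairs, against a mean of 12.62 and a maximum of 26 in shuffled orders.

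Splits of the libraries were used to ask whether chance groupings give as many calls. For any difference among the 4 groups (333 features by limma's F test), 1 of 100 splits was as large, the real one, and the highest other gave 5. With each stress reassigned within levels of the other, 1 of 100 splits was as large for heat (174 features, highest other 2) and 1 of 100 for low oxygen (413, highest other 136). The share of splits as large was thus under 0.05 for these 3 counts. The averaged comparisons were chosen after the other results had been seen, and their shares are not corrected for that choice. For low oxygen a split other than the real one still called 136 features. For the interaction, with 0 features, 100 of 100 splits were as large and the highest other gave 2. The pairwise comparisons allow only 10 splits, too few for a share under 0.05. In 5 of them 1 of 10 splits, the real one, was as large, with real and highest other counts of 8 and 1 for heat, 191 and 1 for low oxygen, 881 and 1 for both stresses, 16 and 2 for both against low oxygen, and 42 and 2 for thermal against hypoxic. For both stresses against heat, 10 of 10 splits gave at least the 0 features of the real one, and the highest other gave 0.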
